A study of Mus musculus with 39 samples.

How the data were processed

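Bulk RNA-seq was analysed for dura mater, the outer membrane around the brain, and masseter, a jaw-closing muscle, from wild-type mice in a model of referred jaw-muscle pain. Collagenase type I, an enzyme that digests collagen, was injected either into the temporal muscle, which lies on the side of the skull, or into the masseter itself. Groups were taken from the treatment and time labels of each sample. Dura was collected 2 days after 10 U of collagenase in the temporal muscle (12 libraries), after saline in the temporal muscle (4 libraries) or after saline at a site the labels do not name (6 libraries). The titles of those 6 use the word naive, while their treatment label reads saline; the label was followed. Masseter was collected after 4 injections of 0.2 to 0.5 U of collagenase into the masseter, at day 38 (3 libraries) and day 52 (3 libraries), after the same doses into the temporal muscle at day 28 (3 libraries), and after saline in the masseter at day 28 (4 libraries) and day 38 (4 libraries).

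Per the labels' protocols, messenger RNA was selected from total RNA with oligo-dT beads, and libraries marked with strand were sequenced as single-end reads on a HiSeq instrument or as paired-end reads on a NovaSeq instrument; which library had which layout is not given in the sources used here. Per the submitters' processing notes, bcl2fastq, Trim Galore and RSEM were used with the mouse genome build mm10. The aligner, the tool versions, the annotation release and the strand setting are not given in the sources used here. The deposited expected counts are RSEM's estimated counts per gene, which need not be whole and are not scaled between libraries, per the file headers. The deposited TPM values are RSEM's transcripts per M transcripts within each library, per the file headers. The deposited FPKM values, RSEM's fragments per kilobase and M mapped fragments per the file headers, were not used. The deposited length and effective length of each gene were used to tell the read layouts apart: the median of length minus effective length, over genes with more than 50 expected counts, was 49.49 to 49.55 bases in 14 libraries, called single-end here, and 212.5 to 237 bases in 25 libraries, called paired-end. The dividing value was 60 bases.

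Expected counts were rounded to whole numbers. Totals ran from 12.1 to 32.3 M (mega) counts per library. The files hold 23412 gene symbols, of which 21563 matched a RefSeq gene table of the same build, used for chromosome positions. Among the 108 pairs of libraries within a group, the chi-square per gene of the counts was 15.6 to 592, so no pair agreed within sampling noise and each library was counted once. The labels do not say that libraries came from separate animals, so p-values measure the spread between these samples. Intervals and floors cover counting error only. Genes with near-identical copies (pseudogenes, paralogs such as Hba-a1 and Hba-a2, multigene families) are uncertain, because RSEM divides ambiguous reads between them.

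Each tissue was fitted once with all of its groups by edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and the quasi-likelihood test for each contrast with Benjamini-Hochberg adjustment. A gene was called when its adjusted p was under 0.05. After filtering, 16363 genes were tested in dura and 14652 in masseter. Levels are counts per M counts (CPM) on TMM-scaled library sizes, given as mean ± SD over the libraries of a group. Log2 fold changes are given with the standard error implied by the F statistic. Every adjusted p in the text is from this test unless another tool is named. For dura, a gene called in the same direction against both control groups was counted once more; the same was done for the masseter after collagenase in the temporal muscle against both saline groups. A fold change against libraries that were all at 0 is given as a lower bound, with 3 counts in each such library; with 1 to 3 control counts the ratio of summed counts is given with its exact 95% interval.

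The choices of groups, tests, gene lists, named genes and alternatives were made before the data were examined, except where the text says otherwise. For each main comparison the named genes were the 10 with the largest rise and the 10 with the largest fall among called genes with an absolute log2 fold change of at least 1, a mean of at least 5 CPM in a group compared and no overlap between the libraries of the groups. Predicted genes and clone names were left out. Up to 4 members with the smallest p of each list described, and 13 genes of inflammation, pain and matrix, could also be named. Other genes, among them markers of neighbouring tissues, the genes behind the count of 14 between days and those that mark the libraries with Xist or Ddx3y, were chosen after their values were seen. In all, 47 gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists of a comparison. Camera with the preset correlation made 203 list calls over 10 comparisons, fry made 99, and 7 held with the estimated correlation. Those 7 were gland markers in dura, for collagenase and for saline against saline in the temporal muscle, neuronal markers in masseter, for saline day 28 against collagenase in the temporal muscle and against saline day 38, and sex-linked genes in the 3 comparisons of masseter groups with and without Xist.

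The steps were tested on simulated data with 200 changed genes and real means, spreads and library sizes. The means were pooled over the groups of a tissue, and the genes of the oxidative phosphorylation list were also raised 2-fold. Each gene was drawn independently, with no layout difference and no shift shared by many genes of a library. The rates below therefore do not cover false calls from such structure in the real libraries. For dura against saline in the temporal muscle, 60.6% of genes changed 2-fold and 84% of genes changed 4-fold were recovered, with 5.42% false calls; against saline, 70.7%, 86% and 1.70%. For masseter injected with collagenase, the values were 46%, 90% and 2.42% at day 38 and 58.6%, 77% and 3.03% at day 52. For masseter after collagenase in the temporal muscle, they were 64%, 80.8% and 2.89% against saline day 28, and 52%, 81% and 6.55% against saline day 38.

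The alternatives were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, limma on log2(TPM + 0.5), an offset for effective length, no filter, a stricter filter (a mean of at least 1 CPM in each group), a fit of the compared groups alone, a 2-fold minimum, other control groups, a replicate block and leaving out each library in turn. Added after the data were seen were fits without libraries rich in brain, muscle or gland transcripts and a fit with the trend on transcript length removed. Other splits of the libraries were drawn up to 60 times. Correlations across libraries were tested with 100000 permutations.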

Results

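Messenger RNA was measured in 39 mouse libraries, 22 from dura mater and 17 from masseter muscle. The dura libraries came from mice 2 days after collagenase in the temporal muscle (12 libraries, 18.2 to 27.2 M (mega) counts each), after saline in the temporal muscle (4 libraries, 19.7 to 32.3 M) or after saline at an unnamed site (6 libraries, 23.1 to 26.3 M). The masseter libraries came from mice given collagenase in the masseter and studied at day 38 (3 libraries, 25.0 to 28.0 M) or day 52 (3 libraries, 12.1 to 24.5 M), from mice given collagenase in the temporal muscle and studied at day 28 (3 libraries, 18.9 to 21.5 M), and from mice given saline in the masseter and studied at day 28 (4 libraries, 18.0 to 23.0 M) or day 38 (4 libraries, 21.0 to 28.1 M). There was no saline group at day 52 and no masseter group given saline in the temporal muscle.

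The groups differed in read layout and in sex-linked genes. All 12 dura collagenase libraries were paired-end and all 10 dura controls were single-end, so in dura the treatment and the layout cannot be told apart. In masseter, the 4 saline day 28 libraries were single-end and the other 13 were paired-end. Xist, the RNA of the inactive X chromosome, was at 531 to 622 CPM in dura collagenase libraries 7 to 12 and at no more than 0.842 CPM in libraries 1 to 6. The Y-linked gene Ddx3y was at 61.1 to 97.1 CPM in dura collagenase libraries 1 to 6, and at 11.9 to 28.8 CPM in all 4 libraries of saline in the temporal muscle. Sex-linked genes were thus not matched between collagenase and saline in the temporal muscle either. In masseter, Xist was at 378 to 492.6 CPM after collagenase in the temporal muscle and at 283 to 332 CPM in saline day 28, while Ddx3y was at 70.1 to 158 CPM in saline day 38 and after collagenase in the masseter. The titles of the saline day 28 libraries carry the letter F.

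**Figure D1:**
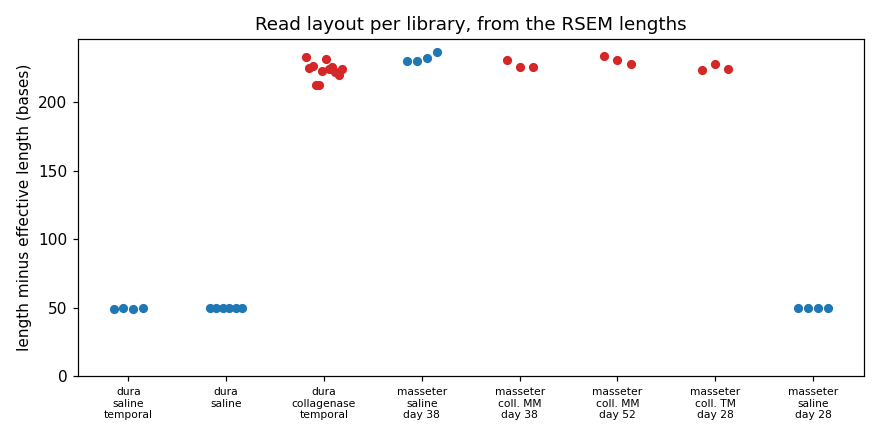
Length minus effective length (bases, y axis) for each library (points) in the 8 groups; red points are collagenase and blue points saline. The 14 single-end libraries sit at 49.49 to 49.55 bases and the 25 paired-end libraries at 212.5 to 237 bases.

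The first comparison asks which transcripts in the dura differ 2 days after collagenase was injected into the overlying temporal muscle. Malat1, a nuclear long non-coding RNA (chromosome 19, 5795690 to 5802672, mm10), was at 3281 ± 1050 CPM (SD, n = 12) after collagenase, against 201 ± 16.6 CPM (n = 4) after saline in the temporal muscle and 190.3 ± 16.97 CPM (n = 6) after saline. Klf9, a transcription factor induced by glucocorticoids (chromosome 19, 23141226 to 23168129), was at 138 ± 19.5 CPM against 35.8 ± 8.90 and 35.0 ± 3.91 CPM. The log2 fold change of Klf9 was 1.94 ± 0.15 (adjusted p = 1.14e-08) against saline in the temporal muscle and 1.98 ± 0.13 (adjusted p = 3.03e-10) against saline. The transcriptional repressor Zbtb20 rose by log2 4.48 ± 0.24 (adjusted p = 3.60e-11) and 4.24 ± 0.20 (adjusted p = 2.16e-12) against the same controls, and Sox4, a transcription factor of progenitor cells, by 3.33 ± 0.32 (adjusted p = 2.23e-07) and 3.28 ± 0.27. Each of the 12 collagenase libraries was above each of the 10 controls for Malat1, Klf9, Zbtb20 and Sox4.

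Some stress and hormone response genes were higher in dura after collagenase. For scale, of all 16363 genes tested, 2179 rose and 1818 fell against saline in the temporal muscle, and 3509 rose and 2503 fell against saline. Of 22 measured heat shock and unfolded protein genes, 10 rose and 0 fell against saline in the temporal muscle (12 rose adjusted over the list alone; camera adjusted p = 1.53e-04, adjusted p = 0.815 with an estimated correlation). Against saline, 9 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.873 with an estimated correlation). Among them, the inducible chaperone Hspa1b was at 60.8 ± 40.9 CPM, with log2 fold changes of 1.45 ± 0.38 (adjusted p = 0.00861) and 1.47 ± 0.32 (adjusted p = 0.00204), and the chaperone Hsph1 rose by log2 0.70 ± 0.14 (adjusted p = 9.93e-04) and 1.14 ± 0.12. In masseter, Hsph1 was also higher in paired-end saline day 38 than in single-end saline day 28 (log2 0.92, adjusted p = 0.0164), while Hspa1b differed by 0.07 (adjusted p = 0.945). Of 16 glucocorticoid response genes, 8 rose and 1 fell against saline in the temporal muscle (10 and 1 adjusted over the list alone; camera adjusted p = 0.00464, adjusted p = 0.781 with an estimated correlation), and 5 rose and 1 fell against saline (camera adjusted p = 0.0756). Fkbp5, a chaperone that restrains the glucocorticoid receptor, had a log2 fold change of 0.95 ± 0.31 (adjusted p = 0.0300) and 0.99 ± 0.27 (adjusted p = 0.00762). Against saline in the temporal muscle, the Fkbp5 call was lost without saline library 2 (adjusted p = 0.124) or 3 (adjusted p = 0.115), with the length trend removed (log2 0.86, adjusted p = 0.0543) and in a fit of those groups alone (log2 0.96, adjusted p = 0.0708); over the fits without 1 library the log2 fold change was 0.72 to 1.19. Of 23 immediate early genes, 4 rose against saline in the temporal muscle and 6 against saline, with camera adjusted p = 0.185 and 0.258; Jund rose by log2 1.10 ± 0.13 (adjusted p = 2.83e-06) and 0.66 ± 0.11 (adjusted p = 1.21e-04).

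Some lymphocyte and myeloid transcripts were lower in dura after collagenase, by amounts that depended on the control. Of 17 B cell and plasma cell genes, 10 fell and 1 rose against saline in the temporal muscle (13 and 1 adjusted over the list alone; camera adjusted p = 2.14e-09, adjusted p = 0.488 with an estimated correlation). Against saline, 8 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.873 with an estimated correlation). Cd79a, a chain of the B cell receptor, was at 5.89 ± 2.86 CPM against 31.5 ± 3.31 CPM after saline in the temporal muscle (log2 -2.42 ± 0.28, adjusted p = 2.60e-06) and 12.1 ± 2.62 CPM after saline (log2 -1.04 ± 0.26, adjusted p = 0.00468). Of 21 macrophage genes, 3 fell and 1 rose against saline in the temporal muscle (camera adjusted p = 0.119), and 13 fell and 0 rose against saline (14 fell adjusted over the list alone; camera adjusted p = 7.93e-06, adjusted p = 0.873 with an estimated correlation). Cd68, a lysosomal protein of macrophages, fell in both comparisons, with log2 -1.17 ± 0.23 (adjusted p = 8.15e-04) and -1.40 ± 0.20 (adjusted p = 3.31e-05). Of 17 neutrophil genes, 11 fell and 0 rose against saline in the temporal muscle (12 fell adjusted over the list alone; camera adjusted p = 1.22e-08, adjusted p = 0.781 with an estimated correlation), while against saline 1 fell and 0 rose (0 adjusted over the list alone; camera adjusted p = 0.324). In masseter, Cd79a was also lower in saline day 38, paired-end, than in saline day 28, single-end (log2 -6.71, adjusted p = 0.0259), groups that also differ in day and in Xist. Cd68 (log2 0.52, adjusted p = 0.371) was not called there, nor was the myeloid adaptor Tyrobp (0.82, adjusted p = 0.204), and its relative Fcer1g was higher in saline day 38 (0.98, adjusted p = 0.0396). In dura, Tyrobp and Fcer1g fell against saline in the temporal muscle (adjusted p = 0.0122 and 0.00835) and against saline (adjusted p = 4.85e-04 and 0.00124). With an offset for effective length both calls against saline in the temporal muscle ended (log2 -0.37 and -0.64, adjusted p = 0.241 and 0.0811). That of Tyrobp also ended with limma on TPM (adjusted p = 0.169) and with the length trend removed (adjusted p = 0.0556).

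The lists of pain channels, pain mediators, and cytokines and chemokines were not called by camera in dura against either control. The potassium channel Kcnk2, which responds to stretch and heat, rose by log2 1.17 ± 0.15 (adjusted p = 9.34e-06) and 0.61 ± 0.12 (adjusted p = 0.00108). Of 24 ion channels of pain, 4 rose and 3 fell against saline in the temporal muscle, and 9 rose and 1 fell against saline (camera adjusted p = 0.767 and 0.661). Of 33 pain mediators and receptors, 4 rose in each comparison, while 3 and 2 fell (camera adjusted p = 0.968 and 0.974). Of 26 cytokines and chemokines, 2 rose in each, while 1 and 0 fell (camera adjusted p = 0.604 and 0.205). Over all 16363 genes tested, 3997 were called against saline in the temporal muscle and 6012 against saline. The chemokine Ccl2 had a log2 fold change of -0.25 (adjusted p = 0.644) and -0.33 (adjusted p = 0.425), the prostaglandin synthase Ptgs2 0.59 (adjusted p = 0.277) and 0.45 (adjusted p = 0.299), and the protease inhibitor Timp1 -0.21 (adjusted p = 0.675) and -1.31 (adjusted p = 0.00220).

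Some of the largest changes in dura lay in genes with near-identical copies. Hba-a1, an alpha globin gene, was at 3.04 CPM after collagenase against 1730.3 and 1334 CPM in the controls, while its twin Hba-a2 was at 734 CPM against 91.9 and 63.9 CPM. Their sum was 737 ± 643 CPM after collagenase against 1822 ± 532 and 1398 ± 488 CPM. The ribosomal protein gene Rpl26 (chromosome 11, 68901566 to 68904534) was listed at 0 in all 10 controls and was at least 79.8-fold higher than saline in the temporal muscle and at least 78.5-fold higher than saline, with 3 counts per library as the floor. The pseudogene Rpl31-ps12 fell by log2 -7.45 and -7.48, and H2-L, a histocompatibility gene, by -6.84 and -7.42. Between paired-end saline day 38 and single-end saline day 28 in masseter, the log2 differences were 10.04 for Rpl26, -7.70 for Rpl31-ps12, -5.74 for H2-L and 3.00 ± 0.13 for the glycolytic enzyme Gapdh. The same differences were 0.31 for Malat1 (adjusted p = 0.456), 0.36 for Zbtb20 (adjusted p = 0.0678), -0.17 for Sox4 and -0.08 for Klf9 (adjusted p = 0.606).

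Transcripts of neighbouring tissues varied between dura libraries. Gad1, the enzyme that makes the inhibitory transmitter GABA in neurons, was at 1741 and 1831 CPM in collagenase libraries 1 and 7 and at no more than 11.4 CPM in the other 10. Ckm, the creatine kinase of muscle, was at 9400 CPM in collagenase library 4, 2651 CPM in library 8 and 821 CPM in library 7, against 12.5 to 34.0 CPM after saline in the temporal muscle and 0.0385 to 0.450 CPM after saline. Against saline, 22 of 23 skeletal muscle genes rose (22 adjusted over the list alone; camera adjusted p = 5.03e-05, adjusted p = 0.873 with an estimated correlation). The pituitary hormone Gh was at 1093 CPM in collagenase library 6.

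In all, 3997 of 16363 genes differed from saline in the temporal muscle (2179 higher, 1818 lower) and 6012 differed from saline (3509 higher, 2503 lower). The number called the same way against both controls was 2358 (1338 higher, 1020 lower). Leaving out library 2 of saline in the temporal muscle lowered the first count to 2662. With TPM in place of counts, the splits were 1243 higher and 1958 lower, 1685 higher and 2245 lower, and 677 higher and 911 lower. The fold changes also followed transcript length: the Spearman correlation across genes, which are not independent replicates, was 0.36 against saline in the temporal muscle and 0.38 against saline.

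**Figure D2:**
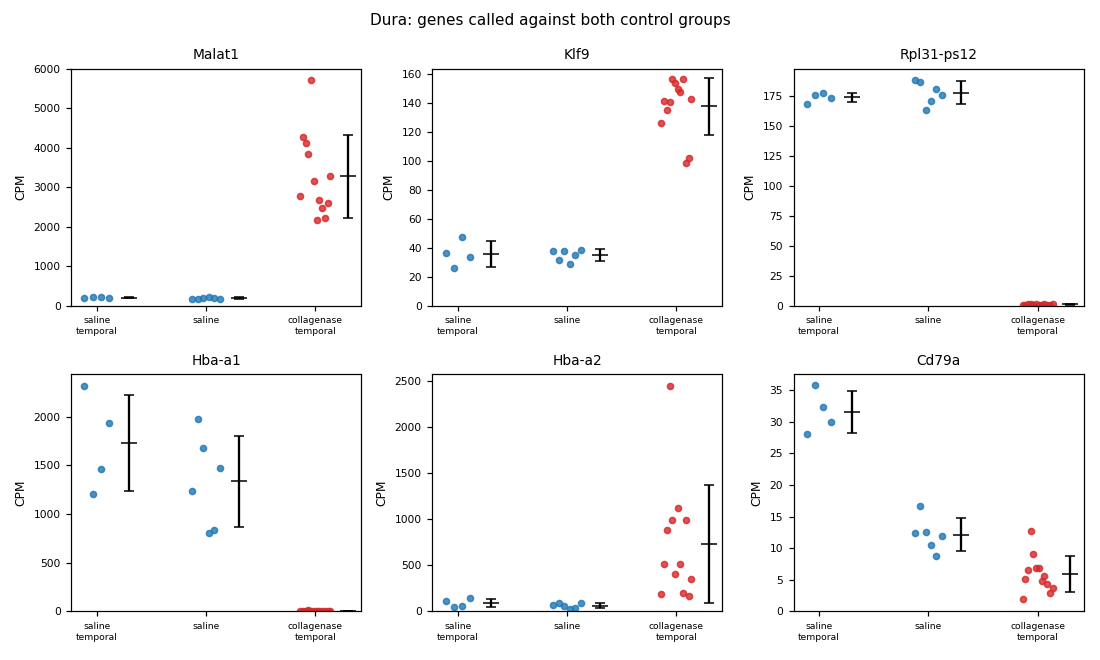
Levels (CPM, linear axis from 0) of 6 genes in dura libraries after saline in the temporal muscle (n = 4), saline (n = 6) and collagenase in the temporal muscle (n = 12); points are libraries, red for collagenase and blue for saline, and the black mark is the mean ± SD. Malat1 and Klf9 are higher in each collagenase library than in each control, and Hba-a1 and Hba-a2 move in opposite directions.

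The dura control groups were compared to ask how far saline at the unnamed site differed from saline in the temporal muscle, both single-end. Directions here are those of saline at the unnamed site relative to saline in the temporal muscle. Of 17 osteoblast and bone genes, 1 was higher over all genes tested and 12 adjusted over the list alone (camera adjusted p = 3.53e-09, adjusted p = 0.429 with an estimated correlation). Of 13 gland genes, 4 were lower (6 adjusted over the list alone; camera adjusted p = 7.35e-28, adjusted p = 1.64e-07 with an estimated correlation). Of 17 neutrophil genes, 4 were lower (13 adjusted over the list alone; camera adjusted p = 1.22e-09, adjusted p = 0.529 with an estimated correlation). In total, 367 genes were higher and 329 lower in saline at the unnamed site than in saline in the temporal muscle, 696 in all. That fit shares its estimate of the spread with the collagenase libraries. A fit of the control groups alone called 4659 genes, so 696 is not a firm measure of how little they differ. The count was 212 without library 3 of saline in the temporal muscle, 216 without library 2 and 1056 without library 1, and 366 and 392 without saline libraries F1 and F2.

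Within dura saline, the titles carry the letters F and M (3 libraries each), and 6 genes differed between them. Xist (log2 8.36 ± 0.34, adjusted p = 1.76e-04) and the X-linked gene Eif2s3x (0.70 ± 0.05, adjusted p = 0.00564) were higher in F. The Y-linked genes Eif2s3y (-9.88 ± 0.25, adjusted p = 8.99e-06), Ddx3y (-9.40 ± 0.44), Kdm5d (-9.22 ± 0.43) and Uty (-7.92 ± 0.40) were lower. These genes were chosen after their values were seen.

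The second tissue asks what repeated collagenase did in the injected masseter itself. At day 38 it was compared with saline day 38, with both groups paired-end. Sln, sarcolipin, a small inhibitor of the calcium pump of muscle (chromosome 9, 53850251 to 53853849), was at 24.3 ± 9.48 CPM (n = 3) against 0.616 ± 0.402 CPM (n = 4; log2 5.25 ± 0.46, adjusted p = 2.14e-04). Myl4, the embryonic myosin light chain, was at 49.9 ± 61.1 against 2.19 ± 0.724 CPM (log2 4.51 ± 0.63, adjusted p = 0.00932), and Gdf15, a stress-induced hormone, at 2.38 ± 0.493 against 0.215 CPM (log2 3.46 ± 0.47, adjusted p = 0.00925). The macrophage elastase Mmp12 was at 3.51 ± 1.59 against 0.119 CPM (log2 4.82 ± 0.52, adjusted p = 9.32e-04). Chrng, the fetal subunit of the muscle acetylcholine receptor, rose by log2 6.14 ± 0.90 (adjusted p = 0.00953), and the embryonic myosin heavy chain Myh3 by 5.79 ± 0.95 (adjusted p = 0.0188). Chrna9, another acetylcholine receptor subunit, fell to 1.71 ± 0.259 from 9.45 ± 1.83 CPM (adjusted p = 0.0444). For Sln, Myl4, Mmp12, Gdf15, Chrng, Myh3 and Chrna9, the 3 collagenase libraries did not overlap the 4 saline libraries.

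Library 5 held much of the size of the Myl4, Chrng and Myh3 changes. Myl4 was at 120.0, 19.5 and 10.0 CPM in libraries 5, 6 and 7, and Myh3 at 137, 8.39 and 5.20 CPM. Without library 5 the log2 fold change was 2.75 for Myl4, 4.24 for Chrng and 2.90 for Myh3, all still called, and without saline library 2 that of Chrng was 6.93. Without library 5 that of Sln was 5.01, and over all fits without 1 library Mmp12 stayed at 4.498 to 5.138, Gdf15 at 3.15 to 3.77 and Chrna9 at -2.59 to -2.34. The Chrng call was lost without saline library 3 (adjusted p = 0.0511) or 4 (adjusted p = 0.0607), and the Myh3 call without saline library 1, 3 or 4 (adjusted p = 0.0693, 0.0639 and 0.0702). The Chrna9 call was lost without any 1 of saline libraries 1, 3 and 4 (adjusted p = 0.0892, 0.0858 and 0.130) or collagenase libraries 5, 6 and 7 (adjusted p = 0.136, 0.136 and 0.153). In a fit of these groups alone the calls of Myl4, Chrng and Myh3 ended, with TPM those of Chrng and Myh3, with limma voom that of Myh3, and with no filter that of Chrna9. Their log2 fold changes in the fit of these groups alone were 4.51, 6.16 and 5.79, those of Chrng and Myh3 with TPM 2.75 and 2.81, that of Myh3 with limma voom 4.61 and that of Chrna9 with no filter -2.47. Sln kept its call in all of these fits.

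At day 38, few genes of the following lists passed over all genes tested. Of 21 macrophage genes, 1 rose and 0 fell (5 rose adjusted over the list alone; camera adjusted p = 3.49e-09, adjusted p = 0.359 with an estimated correlation). Of 25 cell cycle genes, 0 were called over all genes tested and 15 rose adjusted over the list alone (camera adjusted p = 5.78e-12, adjusted p = 0.359 with an estimated correlation). Marrow and bone genes were also present in this group: the granulocyte precursor genes Elane, Prtn3, Mpo and Ctsg summed to 12.1 CPM in library 6, against at most 0.200 CPM in saline day 38, and the bone gene Bglap reached 34.7 CPM, against at most 2.66 CPM. Of 15 slow fibre genes, 3 rose (5 adjusted over the list alone; camera adjusted p = 8.15e-07, adjusted p = 0.235 with an estimated correlation). Of 21 muscle regeneration genes, 4 rose (5 adjusted over the list alone; camera adjusted p = 0.00139, adjusted p = 0.53 with an estimated correlation), with a list median of log2 0.22 that changed sign with TPM. Of 24 matrix proteases and inhibitors, 1 rose (4 adjusted over the list alone; camera adjusted p = 2.42e-05, adjusted p = 0.359 with an estimated correlation). The collagen gene Col1a1 had a log2 fold change of 0.72 (adjusted p = 0.559) and Timp1 of 2.22 (adjusted p = 0.0789). Timp1 was called by DESeq2 (log2 2.23, adjusted p = 0.00711) and limma voom (log2 2.27, adjusted p = 0.0104), and in 0 of 7 edgeR fits without 1 library. With TPM the median log2 fold change of all genes was -0.17, against 0.01 with TMM.

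At day 38, 127 genes were called (49 higher, 78 lower), a count that moved with each library. It was 19, 660, 16 and 11 without saline library 1, 2, 3 or 4, and 13, 22 and 31 without collagenase library 5, 6 or 7. It was 14 in a fit of the compared groups alone, and 39 higher and 34 lower with no filter. The salivary gene Bpifa2 was at 93656 CPM in collagenase library 7 and 21800 CPM in saline library 2, against 3.82 to 19.9 CPM in the masseter libraries with little of it. Without the 5 masseter libraries richest in gland transcripts, 9 genes were called at day 38, among them Sln (adjusted p = 0.00972), Myl4 (adjusted p = 0.0305), Chrng and Chrna9 (adjusted p = 0.0402), while Myh3, Mmp12 and Gdf15 were no longer called (adjusted p = 0.0574, 0.0528 and 0.0678). With those fewer libraries the log2 fold changes of Myh3, Mmp12 and Gdf15 were 6.57, 4.28 and 3.59, against 5.79, 4.82 and 3.46 with all.

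At day 52, the injected masseter was compared with saline day 38, as no saline group of that day was measured. Sln was at 10.1 ± 4.44 CPM (n = 3; log2 3.99 ± 0.45, adjusted p = 0.00202), Mmp12 at 3.98 ± 1.79 CPM (log2 5.02 ± 0.52, adjusted p = 0.00162) and Gdf15 at 2.77 ± 1.68 CPM (adjusted p = 0.00328). Mrgprg, a receptor of sensory neurons, was at 2.18, 24.5 and 3.41 CPM in libraries 8, 9 and 10, against 2 counts over the 4 saline libraries, a ratio of 549 (95% interval 151 to 4541; adjusted p = 0.00611). Chrna9 was at 0.696 ± 0.101 CPM (log2 -3.75 ± 0.57, adjusted p = 0.00780) and the crystallin gene Crybb1 at 3.58 ± 0.526 CPM (log2 -1.70 ± 0.24, adjusted p = 0.00495). The endothelial cadherin Cdh5 was lower, at 176 ± 16.3 against 291 ± 15.1 CPM (log2 -0.73 ± 0.12, adjusted p = 0.0137), and Notch3, a receptor of vascular smooth muscle and pericytes, fell by log2 -0.71 ± 0.11 (adjusted p = 0.0104). The same 2 genes were at 162 to 190 and 48.9 to 58.3 CPM in saline day 28, which was single-end. For all 8 genes named here the 3 collagenase libraries did not overlap saline day 38.

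At day 52, few genes of the following lists passed over all genes tested. Of 23 endothelial genes, 2 fell and 0 rose (9 fell adjusted over the list alone; camera adjusted p = 6.22e-09, adjusted p = 0.171 with an estimated correlation), and of 16 pericyte genes, 3 fell (6 adjusted over the list alone; camera adjusted p = 1.05e-05, adjusted p = 0.219 with an estimated correlation). Of 21 macrophage genes, 0 were called over all genes and 6 rose adjusted over the list alone (camera adjusted p = 1.08e-09, adjusted p = 0.235 with an estimated correlation). Of 20 cytokines and chemokines, 1 rose (6 adjusted over the list alone; camera adjusted p = 3.70e-05, adjusted p = 0.171 with an estimated correlation), and of 24 immediate early genes, 1 rose (14 adjusted over the list alone; camera adjusted p = 1.08e-09, adjusted p = 0.171 with an estimated correlation). Library 10 also held marrow genes, with Elane, Prtn3, Mpo and Ctsg summing to 29.3 CPM, against 0.174 and 0.137 CPM in libraries 8 and 9, while Ccl2 was at 13.2 CPM in library 8, against 2.47 and 1.67 CPM in libraries 9 and 10. With TPM the median of all genes was 0.13, against 0.01 with TMM.

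At day 52, 111 genes were called (42 higher, 69 lower), or 14 higher and 3 lower with TPM. The count was 33 without collagenase library 10, 52 without library 9, and 64, 68, 48 and 50 without saline library 1, 2, 3 or 4. Without library 10 the adjusted p was 0.0507 for Chrna9 and 0.0629 for Cdh5, and the log2 fold change of Gdf15 was 3.08 (3.69 with all libraries). Without library 8 the adjusted p of Cdh5 was 0.0501, and without library 9 the log2 fold change of Mrgprg was 6.70 (8.54 with all libraries). Over the fits without 1 library the log2 fold change was -3.88 to -3.62 for Chrna9 and -0.80 to -0.66 for Cdh5. The calls of Cdh5 and Notch3 ended with TPM (log2 -0.59 and -0.56), and without the 5 gland-rich libraries those of Mrgprg, Gdf15, Crybb1, Cdh5 and Notch3 ended, while Sln, Mmp12 and Chrna9 kept theirs. The log2 fold changes without these libraries were 9.02 for Mrgprg, 3.67 for Gdf15, -1.74 for Crybb1, -0.71 for Cdh5 and -0.73 for Notch3, against 8.54, 3.69, -1.70, -0.73 and -0.71 with all.

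Days 52 and 38 of collagenase in the masseter differed in 14 genes (11 higher and 3 lower at day 52) by the edgeR test, with adjusted p between 0.0333 and 0.0479. The lactate transporter Slc16a3 (log2 -0.97) and its partner Bsg (-0.47) were among the 3 lower genes. These were named after their values were seen. The count was 0 without library 5, 6, 7 or 8, 1 without library 9 and 2 without library 10 by the same test. At an unadjusted p under 0.05, 2724 genes differed, and DESeq2 called 779 and limma voom 1135 (741 higher, 394 lower). With TPM, 698 genes were higher and 0 lower, and the median of all genes was 0.29.

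Both days shared 22 called genes, 10 higher, among them Sln, Myl4, Mmp12 and Gdf15, and 12 lower, among them Chrna9 and Crybb1. Both lists used the same 4 saline libraries. With independent lists 0.140 higher and 0.367 lower genes would be shared. Simulated data with the shared controls gave at most 0 in 20 runs. They held no treatment effect, so they cannot show how many genes shared controls add to lists of this size. With the saline libraries divided between the days, 2 to 8 genes were shared.

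**Figure D3:**
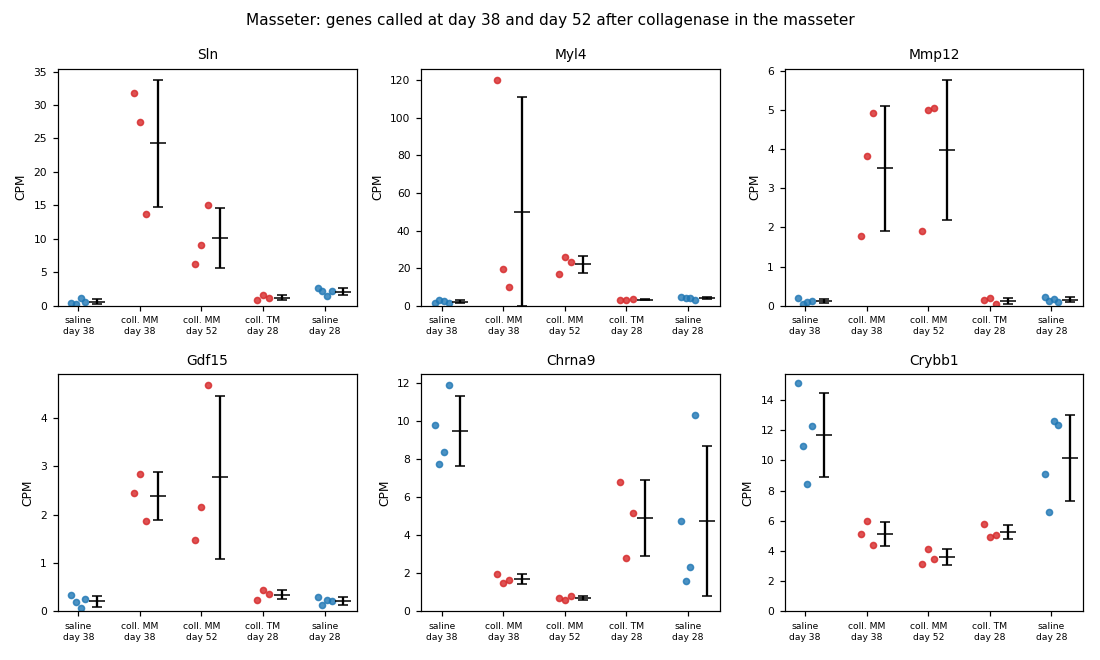
Levels (CPM, linear axis from 0) of Sln, Myl4, Mmp12, Gdf15, Chrna9 and Crybb1 in masseter libraries of 5 groups (collagenase in the masseter, MM, or in the temporal muscle, TM); points are libraries, red for collagenase and blue for saline, and the black mark is the mean ± SD. Sln is at 13.6 to 31.8 CPM at day 38 and 6.27 to 15.0 CPM at day 52 of collagenase in the masseter, against 0.301 to 1.19 CPM in saline day 38.

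The referred comparison asks what changed in the masseter when collagenase was injected into the temporal muscle instead. Neither saline group matched the treated libraries in all else, as both had saline in the masseter itself. Saline day 28 was also single-end, and saline day 38 was of another day and had Ddx3y in place of Xist. Granulocyte genes were higher at day 28 than in either saline group. Camp, an antimicrobial peptide of neutrophil granules (chromosome 9, 109847377 to 109849456), was at 32.3 ± 25.1 CPM (n = 3) against 2.54 ± 0.362 CPM in saline day 28 (n = 4; log2 3.67 ± 0.90, adjusted p = 0.0432) and 1.90 ± 1.51 CPM in saline day 38 (n = 4; adjusted p = 0.0118). Elane, neutrophil elastase, which is transcribed in marrow precursors, was at 8.91 ± 7.12 CPM, with log2 7.45 ± 1.81 (adjusted p = 0.0421) and a ratio of 442 to the 2 counts of saline day 38 (95% interval 122 to 3658; adjusted p = 0.0143). Col2a1, the collagen of cartilage, was at 21.6 ± 9.41 CPM against 0.727 CPM (log2 4.87 ± 0.74, adjusted p = 0.00329) and 1.58 CPM (log2 3.77 ± 0.70, adjusted p = 0.00460). Fsd2, a muscle protein, fell to 132 ± 4.94 CPM from 266 ± 65.8 CPM (log2 -1.01 ± 0.15, adjusted p = 0.00329) and 300.4 ± 4.77 CPM (log2 -1.19, adjusted p = 5.67e-04). For Camp, Elane, Col2a1 and Fsd2, the 3 collagenase libraries did not overlap the 8 saline libraries.

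Bone, cartilage and cell cycle lists moved with the granulocyte genes. Of 16 neutrophil genes, 7 rose and 0 fell against saline day 28 (14 rose adjusted over the list alone; camera adjusted p = 5.71e-13, adjusted p = 0.242 with an estimated correlation), and 15 rose against saline day 38 (16 adjusted over the list alone; camera adjusted p = 1.32e-11, adjusted p = 0.332 with an estimated correlation). Of 17 osteoblast and bone genes, 3 rose against saline day 28 (13 adjusted over the list alone; camera adjusted p = 5.93e-12, adjusted p = 0.242 with an estimated correlation) and 11 against saline day 38 (16 adjusted over the list alone; camera adjusted p = 8.51e-11, adjusted p = 0.332 with an estimated correlation). Of 10 cartilage genes, 3 and 4 rose (3 and 5 adjusted over the list alone; camera adjusted p = 7.10e-06 and 2.40e-04, adjusted p = 0.228 and 0.332 with an estimated correlation). Of 25 cell cycle genes, 2 and 13 rose (16 and 18 adjusted over the list alone; camera adjusted p = 1.32e-11 and 6.60e-11, adjusted p = 0.271 and 0.332 with an estimated correlation). Ibsp, bone sialoprotein, was at 21.8, 55.8 and 48.9 CPM in collagenase libraries 11, 12 and 13, and also at 49.4 and 10.9 CPM in libraries 6 and 7 of collagenase in the masseter day 38, 23.5 CPM in library 10 of day 52, and 12.6 and 40.2 CPM in saline day 28 libraries 1 and 2. The prostaglandin synthase Ptgs2 had a log2 fold change of 1.35 (adjusted p = 0.0788; 0.0467 without saline day 28 library 3) and 0.42 (adjusted p = 0.538).

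Other muscle genes depended on which saline group was used. Myh4, the fast myosin heavy chain, was at 4229 ± 1175 CPM after collagenase in the temporal muscle, above saline day 28 (1416 CPM, log2 1.58 ± 0.28) and below saline day 38 (28560 CPM, log2 -2.76 ± 0.31). Gapdh likewise had a log2 fold change of 2.34 ± 0.13 against saline day 28, which was single-end, and -0.66 ± 0.13 against saline day 38, which was of another day and had Ddx3y in place of Xist. The Gapdh call against saline day 38 ended with TPM (log2 -0.60, adjusted p = 0.0581) and without the 5 gland-rich libraries (log2 -0.65, adjusted p = 0.121). The Myh4 call against saline day 28 ended without those libraries (log2 1.06, adjusted p = 0.157) and in a fit of the compared groups alone (log2 1.58, adjusted p = 0.111). With TPM the median of all genes against saline day 28 was -0.12, against -0.03 with TMM.

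For the referred masseter, 432 genes were called against saline day 28 (172 higher, 260 lower), 1599 against saline day 38 (750 higher, 849 lower) and 70 against both (52 higher, 18 lower). The first count was 217, 119 and 156 without collagenase library 11, 12 or 13. The second was 935, 662 and 989 without these libraries and 884 without saline day 38 library 3. The third was 8 without library 12, 18 without library 13, 23 without saline day 28 library 4, and 40, 42 and 32 without saline day 38 library 1, 2 or 3. With a length offset, 233 genes were higher and 146 lower against saline day 28, and 54 higher and 9 lower against both. With TPM, 341 were higher and 224 lower against saline day 38, and 22 higher and 1 lower against both. Against saline day 28, the Camp and Elane calls were lost without library 12 (adjusted p = 0.175 and 0.133) or 13 (adjusted p = 0.0942 and 0.0911), and without saline library 1, 2, 3 or 4 (Camp 0.0816, 0.0694, 0.0624 and 0.0912; Elane 0.084, 0.0663, 0.0603 and 0.0902). The Elane call was also lost without library 11 (adjusted p = 0.0515). Against saline day 38, both were lost without library 12 (Camp 0.0612, log2 3.35; Elane 0.0518), and without saline library 1 the log2 fold change of Camp was 4.77 (4.11 with all libraries). The log2 fold changes against saline day 28 were 2.91 to 4.12 for Camp and 6.71 to 7.93 for Elane over these fits. With limma voom the Camp call ended against saline day 28 and the Elane call against both, with TPM and in a fit of the compared groups alone the Camp call ended against saline day 28, and without the 5 gland-rich libraries both ended against both. The log2 fold changes without those libraries were 4.19 and 4.58 for Camp (3.67 and 4.11 with all) and 7.99 and 9.34 for Elane (7.45 and 8.36 with all), against saline day 28 and day 38. Col2a1 and Fsd2 kept their calls without any 1 library against either saline group, the Fsd2 call against saline day 28 ended in a fit of those groups alone (log2 -1.01, adjusted p = 0.102), and without the 5 gland-rich libraries both were called against saline day 38 alone (adjusted p = 0.0307 and 0.0199). Against saline day 28 their log2 fold changes without those libraries were 5.44 (adjusted p = 0.0610) for Col2a1 and -0.83 (adjusted p = 0.132) for Fsd2, against 4.87 and -1.01 with all.

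**Figure D4:**
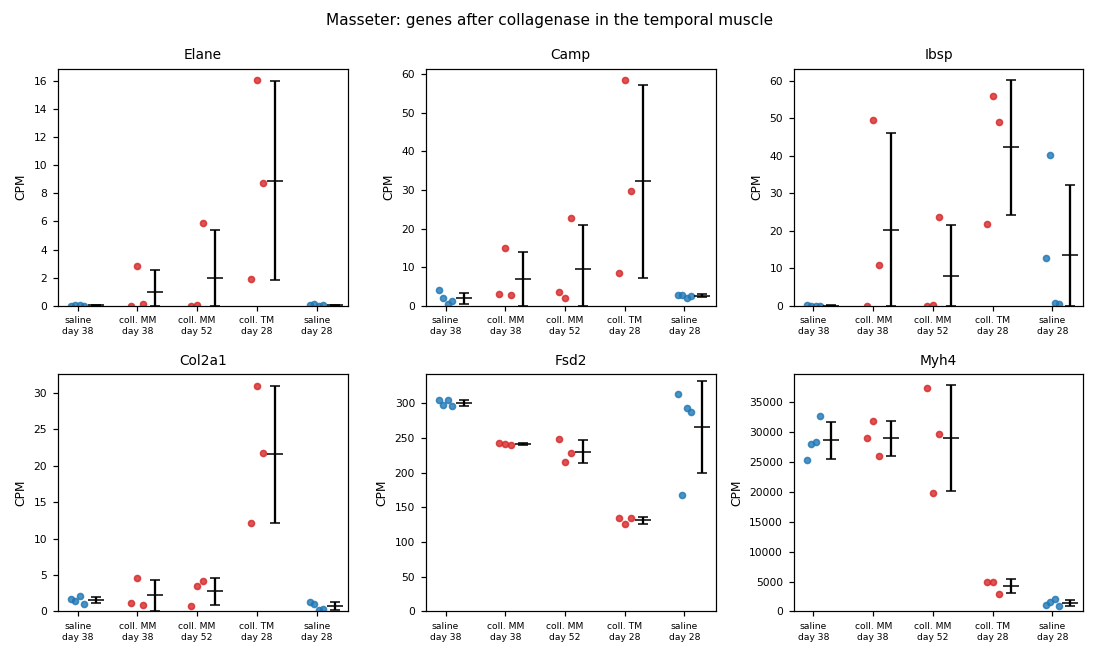
Levels (CPM, linear axis from 0) of Elane, Camp, Ibsp, Col2a1, Fsd2 and Myh4 in masseter libraries of 5 groups (collagenase in the masseter, MM, or in the temporal muscle, TM); points are libraries, red for collagenase and blue for saline, and the black mark is the mean ± SD. Col2a1 is at 12.1 to 31.0 CPM after collagenase in the temporal muscle, against 0.182 to 2.10 CPM in both saline groups.

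The injected and the referred masseter were compared to ask whether they share changes. Of the genes called at day 38 in injected masseter and those called against both saline groups in referred masseter, 1 was shared, Crybb1, lower in both. Its log2 fold change at day 38 stayed at -1.31 to -1.04 without any 1 library, while its call was lost without saline day 38 library 1, 3 or 4 (adjusted p = 0.0829, 0.0511 and 0.110) and without collagenase library 5, 6 or 7 (adjusted p = 0.130, 0.0726 and 0.135). Against the shared saline day 38 libraries, 40 genes were called in the same direction (14 higher, 26 lower) and 6 in opposite directions. Independent lists would share 2.51 and 4.52, and dividing the controls gave 0 to 28. Simulated data with shared controls gave 0, but they too held no treatment effect and cannot show what shared controls add. Against saline day 28 for the referred group, 1 gene was shared, lower, and 5 were opposite, where independent lists would share 0.575 higher and 1.38 lower. A direct test of collagenase in the temporal muscle day 28 against collagenase in the masseter day 38 called 1719 genes (981 higher, 738 lower), and 1101 higher and 97 lower with TPM, where the median of all genes was 0.21. The count was 894 and 786 without library 11 or 12, and 1028, 1059 and 947 without library 5, 6 or 7. These groups also differ in day and in the Xist and Ddx3y pattern, which cannot be told apart from the injection site. In that test 7 of 15 complement genes were lower in referred masseter (12 adjusted over the list alone; camera adjusted p = 8.61e-10, adjusted p = 0.292 with an estimated correlation), as were 6 of 21 macrophage genes (11 adjusted over the list alone; camera adjusted p = 2.13e-06, adjusted p = 0.524 with an estimated correlation).

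The saline groups of masseter differed in 3608 genes (1889 higher and 1719 lower at day 28), or 1406 higher and 458 lower with TPM, where the median of all genes was 0.19 (0.05 with TMM). Without saline day 38 library 3, the count was 2280. Day, layout and the Xist and Ddx3y pattern all differ between these groups and cannot be told apart.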

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

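The tests of other splits of the libraries were planned; all other tests here, on layout, transcript length, brain and muscle RNA, bone and marrow, blood granulocytes, a single library and slow fibres, were chosen only after the results were seen.

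The first pattern is the 2358 genes called in dura after collagenase against both controls. Brain and muscle RNA is not the whole cause, as 2072 of them stayed called the same way without collagenase libraries 1, 4, 7 and 8. A dependence on transcript length may account for part, since 1151 stayed called the same way once each library's length trend was removed, below the 1179 set as the bound by a small margin. Read layout may account for some of the largest changes. Of the 20 genes of largest change, 12 were called the same way between paired-end and single-end masseter saline libraries, and Hba-a1 was not tested there. The direction alone does not give the size. In masseter the log2 difference was 10.04 for Rpl26, 0.98 for Zfp536 and 0.92 for Deptor. In dura against saline in the temporal muscle, they stayed at 10.69 to 10.82, 4.56 to 4.88 and 3.23 to 3.49 over fits without 1 library. Over all dura calls measured in masseter, 21.6% were called the same way and 6.41% the opposite way. The masseter comparison also differs in day and in Xist. Collagenase in the temporal muscle stays open as an explanation, because each collagenase library was paired-end and each control single-end, and the layout and the treatment cannot be told apart.

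The second pattern is the rise of granulocyte, bone and cartilage genes in the masseter after collagenase in the temporal muscle. Granulocytes from blood, without marrow, may be the source. They were taken to keep the log2 ratio of precursor genes (Elane, Prtn3, Mpo and Ctsg) to mature granulocyte genes (Csf3r and Cxcr2) within the range of saline. The ratio was above that range, at 2.11, 2.94 and 2.83 in the 3 libraries and at most 1.21 in saline. The ratio decides nothing, because in saline the precursor genes summed to at most 0.714 CPM and they belong to the pattern itself. Bone and marrow in the dissected samples may also be the source: over the 10 paired-end libraries of other groups, bone and granulocyte levels gave Spearman rho = 0.503 (permutation p = 0.145) and Pearson r = 0.908 (permutation p = 0.00309), 1 relation tested; without libraries 6 and 10, r was 0.549 and rho 0.0476, so the relation rests on those libraries and decides nothing. A referred effect of collagenase on marrow, bone or muscle was not tested apart from this and stays open. Both saline groups also differ from these libraries in injection site, and each in layout or in day and Xist.

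The third pattern is the genes called higher in injected masseter at day 38. A single library may account for part of it: without library 5 the median log2 fold change of the 49 genes was 1.43, against 1.96 with it, and 9 were still called, which decides nothing, as the genes were chosen with the other libraries included. More slow-fibre muscle in the samples is argued against by 1 gene, the slow myosin Myh7. Its log2 fold change was 0.19 ± 0.35, against 4.20 for Tnni1, a troponin of slow and embryonic fibres. The slow fibre genes Tnnt1 and Tnnc1 were also called higher (adjusted p = 0.0303 and 0.0444), so Myh7 alone does not settle it. Regenerating fibres after local collagenase may be a source of Myl4, Myh3 and Chrng, a hypothesis drawn from the same libraries that was not tested. Other differences between the samples stay open, since 2 of 35 splits called as many genes.

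For some counts only the real split of the libraries, and no other split drawn, called as many genes. Among 60 splits these were dura against saline (6012, highest other 2834), dura against both controls (2358, highest other 0), the dura controls (696, highest other 1) and referred masseter against both saline groups (70, highest other 62). Among 35 splits they were masseter at day 52 (111, highest other 2), referred masseter against saline day 38 (1599, highest other 100) and the masseter saline groups (3608, highest other 0). That makes chance less likely, but 35 or 60 splits with no correction over the counts cannot exclude it, and 62 lies close to 70. For the genes shared by injected masseter at day 38 and referred masseter against saline day 28, 1 gene was found (1 of 60, highest other 0). A single gene is too few to read, where independent lists would share 1.96. Other splits called as many genes for 3 counts, given with the splits as large, the real one included. They were dura against saline in the temporal muscle (3997, 3 of 60, highest other 5242), masseter at day 38 (127, 2 of 35, highest other 628) and referred masseter against saline day 28 (432, 2 of 35, highest other 531). Splits that call so many genes point to structure among the samples: the highest set collagenase libraries 1, 4, 5 and 7 of dura apart, saline day 38 libraries 1, 3 and 4 against library 2 with the collagenase libraries, and saline day 28 libraries 1, 2 and 4 against library 3 with the collagenase libraries. The splits were too few (10) for days 52 against 38 (14; highest other 1), referred against injected masseter (1719; highest other 0) and letters F against M (6; highest other 0).

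Only the saline groups, of 4 or 6 libraries each, were tested for a library far from the others of its group. The collagenase groups, of 3 or 12 libraries, were outside the sizes tested, so nothing is said of their libraries here. Of 171 groups and measures tested, 10 were found, where chance gives 8.55. Zfp536 was at 0.203 CPM in dura saline library F3, against 0.427 to 0.538 in the others. Hist1h2ao was at 0.149 CPM in library 2 of saline in the temporal muscle and at 0 in the others. The depth of masseter saline day 28 library 4 was 18.0 M, against 22.2 to 23.0 M. In saline day 38, library 1 stood apart for Postn (27.0 CPM, others 16.9 to 18.1) and Vash2 (12.9 CPM, others 5.48 to 6.42), and library 2 for Chrng (0.250 CPM, others 0.0415 to 0.0701). Library 3 of that group stood apart for Lrrc15 (0.947 CPM, others 0.401 to 0.486), Chi3l3 (0.491 CPM, others 0.166 to 0.200), Prtn3 (0 CPM, others 0.0831 to 0.1002) and Ctsg (0.0351 CPM, others 0). By a test of the difference itself, 14 genes differed in their change from saline day 38 between collagenase day 52 and day 38.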

How the results depend on the processing

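The alternatives that leave out several libraries, remove the length trend or fit libraries 1 to 4 with no block were chosen after the data were seen; the others were planned. Of 276 alternative counts, 154 lay within 1.5 times the reported one and 122 moved, 72 of them besides leaving out 1 library. Of 1614 values of named genes, 1420 kept their direction and side of the threshold, 187 kept the direction and lost the call, 4 gained it and 3 reversed. The reversed values were of uncalled genes in dura against saline in the temporal muscle: Ccl2 was at log2 0.0708 without collagenase libraries 1, 4, 7 and 8, and with the length trend removed Ccl2 was at 0.0039 and Timp1 at 0.0192. Unless the construction shows it (fewer libraries or a stricter threshold), the cause was not tested.

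RLE size factors gave 4 genes for day 52 against day 38. DESeq2 gave 1584 for the dura controls, 98 for letters F against M, 718 for masseter day 38, 611 for day 52, 779 for day 52 against 38, 1058 for referred masseter against saline day 28 and 199 against both saline groups. Limma voom gave, in that order without the letters, 4563, 1142, 1431, 1135, 1299 and 384, and also 3617 for dura against both controls, 3537 for referred masseter against saline day 38 and 3328 for referred against injected masseter. TPM gave 3930 for dura against saline, 22 for day 38, 17 for day 52, 698 for day 52 against 38, 184, 565 and 23 for referred masseter against saline day 28, day 38 and both, and 1864 for the saline groups. The length offset gave 53 for day 52 against 38. No filter gave 73 for day 38, 0 for day 52 against 38 and 46 for referred masseter against both; the stricter filter gave 170 for day 52 against 38, and 266 and 30 for referred masseter against saline day 28 and both.

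A fit of the compared groups alone gave 4659 for the dura controls, 14 for day 38, 59 for day 52, 0 for day 52 against 38, 93 and 11 for referred masseter against saline day 28 and both, and 2035 for the saline groups. A 2-fold minimum gave 1021, 1758 and 474 for dura against saline in the temporal muscle, saline and both, 218 for the dura controls, 42 for day 38, 43 for day 52, 2 for day 52 against 38, 207, 551 and 44 for referred masseter against saline day 28, day 38 and both, 1179 for the saline groups, 429 for referred against injected masseter and 0 for their shared genes. Other controls gave 40 shared genes with saline day 38 for both, 6350 for dura with the controls pooled, 1552 for dura against both with odd and even libraries set against 1 control group each, 3277 and 2748 for days 38 and 52 against saline day 28, and 75 for referred masseter against pooled saline. List calls were 7 with an estimated correlation and 99 with fry.

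Without collagenase libraries 1 and 7, 4, 7 and 8, or 1, 4, 7 and 8, the dura controls differed in 2960, 1346 and 3706 genes. Without the 5 gland-rich masseter libraries the counts were 9 for day 38, 17 for day 52, 0 for day 52 against 38, 64, 400 and 2 for referred masseter against saline day 28, day 38 and both, and 319 for referred against injected masseter. Leaving out 1 library gave 2662 to 4323 for dura against saline in the temporal muscle, 4597 to 6393 against saline, 1732 to 2641 against both, 212 to 1056 for the dura controls, 5 to 7 for the letters, 11 to 660 for day 38, 33 to 93 for day 52, 0 to 2 for day 52 against 38, 119 to 633, 662 to 1272 and 8 to 102 for referred masseter against saline day 28, day 38 and both, 2280 to 3732 for the saline groups and 786 to 1293 for referred against injected masseter.

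Libraries with the same number in different groups were not shown to be paired: their correlations ran from -0.196 to 0.195 in dura, where 1 of 4 was highest with its own number, and from -0.215 to 0.242 in masseter saline, where 0 of 4 was. With a replicate block over libraries 1 to 4, 13 genes were called in dura against saline in the temporal muscle and 830 between the saline groups of masseter; the same libraries with no block gave 271 and 2035. Depth limits genes near 0 counts, for which ratios have wide intervals.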

Other observations

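The saline groups of masseter differed in fibre type, nerve and matrix genes. Of 15 slow fibre genes, 9 were higher in saline day 28 than in saline day 38 (12 adjusted over the list alone; camera adjusted p = 1.05e-06, adjusted p = 0.221 with an estimated correlation). Of 18 fast fibre genes, 11 were lower and 1 higher (12 and 3 adjusted over the list alone; camera adjusted p = 1.53e-04, adjusted p = 0.433 with an estimated correlation), as were 10 of 17 glycolysis genes (11 adjusted over the list alone; camera adjusted p = 1.05e-06, adjusted p = 0.294 with an estimated correlation). Of 13 neuronal genes, 8 were higher and 0 lower (9 higher adjusted over the list alone; camera adjusted p = 6.49e-10, adjusted p = 0.00186 with an estimated correlation). The same neuronal list was lower in referred masseter than in saline day 28, with 5 of 13 called (8 adjusted over the list alone; camera adjusted p = 6.59e-14, adjusted p = 0.00175 with an estimated correlation). Of 30 fibrillar collagen and other matrix genes, 17 were lower in saline day 28 than in saline day 38 (20 adjusted over the list alone, camera adjusted p = 3.87e-07, adjusted p = 0.433 with an estimated correlation).

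At day 52 of collagenase in the masseter, antigen presentation, complement and granulocyte lists had 0 calls over all genes. Of 8 class II histocompatibility genes, 0 were called over all genes and 7 rose adjusted over the list alone (camera adjusted p = 7.76e-07, adjusted p = 0.252 with an estimated correlation). Of 15 complement genes, 4 rose adjusted over the list alone (camera adjusted p = 8.06e-08, adjusted p = 0.235 with an estimated correlation), and of 16 neutrophil genes, 0 were called over all genes and 15 rose adjusted over the list alone (camera adjusted p = 7.76e-07, adjusted p = 0.328 with an estimated correlation). The rise of the granulocyte precursor genes and of Camp was in library 10. Elane, Prtn3, Mpo and Ctsg summed to 0.174, 0.137 and 29.3 CPM in libraries 8, 9 and 10. Camp was at 3.66, 2.10 and 22.8 CPM there, against at most 3.98 CPM in saline day 38. The mature granulocyte genes Csf3r and Cxcr2 summed to 2.18, 2.29 and 8.19 CPM, against 0.250 to 1.68 CPM in saline day 38. Between days 52 and 38, 11 of 23 endothelial genes were lower at day 52 adjusted over the list alone (camera adjusted p = 6.15e-08, adjusted p = 0.423 with an estimated correlation). In referred masseter, 13 of 23 endothelial genes were lower than in saline day 38 (16 adjusted over the list alone; camera adjusted p = 2.07e-10, adjusted p = 0.222 with an estimated correlation). Against saline day 28, 0 of the 23 were called (0 adjusted over the list alone; camera adjusted p = 0.612), and saline day 28 itself had 10 lower than saline day 38 (11 adjusted over the list alone; camera adjusted p = 1.05e-06, adjusted p = 0.294 with an estimated correlation).

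Transcripts of salivary and other glands appeared in single masseter libraries across groups. Bpifa2 was at 50004 CPM in library 11 of collagenase in the temporal muscle, and at 31427 and 3566 CPM in saline day 28 libraries 1 and 4. The mucin gene Muc5b was at 649 and 4924 CPM in saline day 28 libraries 1 and 4 and listed at 0 in the 13 paired-end masseter libraries. The sebaceous gland gene Scd3 was at 6156 CPM in saline day 28 library 2 and at no more than 1.64 CPM in the others. These genes were chosen after their values were seen. In dura, 6 of 13 gland genes fell after collagenase against saline in the temporal muscle (7 fell and 2 rose adjusted over the list alone; camera adjusted p = 2.74e-07, adjusted p = 0.0081 with an estimated correlation). Of 5 sex-linked genes, 4 were lower and 1 higher in referred masseter and in saline day 28, each against saline day 38, and in referred against injected masseter (camera adjusted p = 1.27e-30, 4.36e-25 and 6.70e-27, adjusted p = 4.69e-04, 7.01e-04 and 0.00129 with an estimated correlation).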
